A study of Mus musculus with 3 samples.

How the data were processed

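Spatial transcriptomes (10x Genomics Visium) were read from 5 µm transverse sections of hearts fixed in formalin and embedded in paraffin. Each of 3 groups, Ctrl, Ctrl_HF and TTg_HF, had 1 section. The deposited values are raw UMI counts per gene and spot over tissue, made by the authors with Space Ranger 1.0.0 on mm10 (GRCm38), per the submitters' processing notes. Settings of that program are not given in the sources used here. The deposited tables list 19465 genes, of which 1859 had no UMI in any section and 0 were mitochondrial genes. A table of gene names matched 19451 of the identifiers, and 99.33% had a position in GRCm38. A total of 11 symbols occurred more than once.

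UMIs were summed over all deposited spots of a section, since spots are small regions of several cells and not replicates. The 4992 positions of the array held 1935, 2994 and 2157 spots over tissue in Ctrl, Ctrl_HF and TTg_HF. UMIs per spot ranged from 617 to 22476, from 211 to 25445 and from 548 to 16369. The Ctrl_HF section had 73 spots on the outermost lines of the array, so its tissue reached the edge, against 15 spots for TTg_HF and 0 for Ctrl. The 10 most abundant genes took 13.99%, 11.112% and 12.52% of UMIs. Sums were scaled to CPM on effective library sizes from TMM (edgeR 4.0.16, R 4.3.3), with factors of 0.992, 1.02 and 0.985. Neither edgeR nor DESeq2 was used for a test. Levels carry exact Poisson intervals and log2 ratios exact conditional binomial intervals, at 95%, which cover counting error only. A count of 0 was set to a floor of 3 counts, which is 0.175, 0.131 and 0.271 CPM on the same effective sizes in the 3 sections. Each value was also computed in 4 quadrants around the centre of a section.

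With 1 section per group no comparison was tested. Genes with at least 200 UMIs in both sections together, a ratio of at least 1.5-fold and an interval that excluded no difference were counted per direction. For a gene list, the median log2 ratio of members with at least 50 UMIs was set against 10000 random lists of the same size matched on mean expression. A list with at least 4 such members was said to stand apart below percentile 2.5 or above 97.5, a limit that assumes independent genes. The comparisons, these limits, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined, unless stated otherwise.

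Named genes were, in each of the 2 main comparisons, the 12 highest and 12 lowest log2 ratios among genes with at least 200 UMIs in both sections and at least 20 CPM in the higher one. The 4 transgene factors were added, as were up to 4 members with the largest absolute ratio of each list in the text. Col1a1, Col3a1, Postn and Meox1 were added for the matrix and activated fibroblast lists. The X-linked genes Ddx3x, Eif2s3x, Kdm6a and Kdm5c and the neighbouring gene pairs in the closing part were chosen after their values were seen. Some genes that the rule names are not reported here.

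Spots were clustered with scanpy 1.11.5 and leidenalg 0.10.2 (Leiden, resolution 0.5, 15 neighbours, 20 components, 2000 variable genes scaled within each section). Clusters are described by their leading genes, no doublet caller was run, and no cell-type makeup was estimated. The ventricular muscle region was taken as the cluster without 3 or more leading genes from a list of another cell type, a rule written after the clusters were seen. For shares per spot, each spot was thinned to 2500 UMIs, a depth chosen after seeing the data, and shallower spots were left out (4, 131 and 30). Shares of spots carry exact binomial (Clopper-Pearson) intervals, which treat spots as independent draws although spots of a section are not replicates. The other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and scikit-learn 1.9.0.

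The size rule was tested on simulated data drawn from the real genes and section depths. The simulation held counting noise alone, with no spread between animals or sections. Of 50 genes each set 1.5-fold apart, 48% were called over 10173 genes for Ctrl_HF against Ctrl and 52% over 9873 genes for TTg_HF against Ctrl_HF. All 50 genes set 2-fold apart were called in both, and 2 of 9973 and 1 of 9673 genes with no difference were called. The list rule called 5.533% and 4.567% of 3000 unshifted lists and all 20 lists shifted by 0.3 on the log2 scale.

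Gaps between the medians of lists were given bootstrap intervals over their genes (10000 draws), widened for the 10 or 4 pairs compared, which assume independent genes. Other non-muscle cell type lists with at least 4 members were compared in the same way, widened as for 10 pairs, with the members of 5 such lists pooled, after heart muscle genes and shared members were left out. Gaps of the activated fibroblast list were computed inside each region too. Neighbouring pairs were counted among autosomal genes next to each other in gene order whose symbols start differently. This leaves out relatives that share the start of a symbol, but not relatives with unlike symbols. For the relation of the 2 main comparisons, sections that vary independently and sections with counting noise alone were simulated.

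Alternatives were scaling by total UMIs or by DESeq2 1.42.0 size factors, minimum counts of 50 or 1000 UMIs for genes (with 10 or 200 UMIs for list members), a size of 2-fold, spots with at least 1000 UMIs, section edges left out, the ventricular muscle region alone, equal weights for spots, thinning to the shallowest section, a threshold at the 90th percentile of Ctrl, no thinning of spots, the activated fibroblast list in place of the matrix list, and a Leiden resolution of 1.0. Leaving out smooth muscle and blood clusters at that resolution, and leaving out genes of chromosomes X and Y, were added after seeing the data.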

Results

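Transcripts were counted in place over 3 transverse sections of mouse heart, 1 section in each of 3 groups. The mice were hybrids of the C57BL/6 strain and the outbred ICR stock, and their hearts were taken at week 15. All 3 animals are labelled as males that carried a tamoxifen-inducible Cre recombinase driven by Tcf21, a gene of cardiac fibroblasts, and a tdTomato reporter. The Ctrl animal received normal chow. The Ctrl_HF animal had the same genotype and received a diet with 60% of its calories from fat together with L-NAME, an inhibitor of nitric oxide synthases, at 1.0 g/L in the drinking water. That combination models heart failure with preserved ejection fraction, in which the ventricle contracts normally but fills poorly. The TTg_HF animal received the same diet and L-NAME and carried in addition the MGTH2A transgene, which is named for the cardiac reprogramming factors Mef2c, Gata4, Tbx5 and Hand2. Tamoxifen was given at 2 mg per day for 5 days at week 5. The series asks whether cardiac reprogramming and Gata4 reduce fibrosis and diastolic dysfunction in this model.

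The Ctrl section held 1935 spots over tissue and 17304620 unique molecular identifiers (UMIs), with a median of 8625 UMIs and 3333 genes per spot. The Ctrl_HF section held 2994 spots and 22334517 UMIs, with medians of 7237 UMIs and 3047.5 genes. The TTg_HF section was the shallowest, with 2157 spots, 11218170 UMIs and medians of 5003 UMIs and 2324 genes. With 1 section per group, no difference given here has a replicate check, and none was tested. Levels are given as CPM of UMIs summed over a section. Intervals of levels and of gene ratios are 95% intervals that cover counting error only. Intervals of shares of spots treat spots as independent draws, which they are not. Counts of genes by size describe these sections. A gene or list member was counted as higher or lower only with at least 200 UMIs in both sections together, a 1.5-fold ratio and an interval that excluded no difference. The spread over 4 quadrants of a section is a spread inside 1 heart, not between animals.

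The section labelled Ctrl held 0 UMIs of the 11 Y-linked genes in the tables, against 4935 in the Ctrl_HF section and 2698 in the TTg_HF section. A floor of 3 counts in that section is 0.175 CPM for a gene. Eif2s3y stood at 88.5 CPM in Ctrl_HF and 98.0 CPM in TTg_HF, and Ddx3y at 73.1 and 90.8 CPM. The X-linked genes Ddx3x, Eif2s3x, Kdm6a and Kdm5c, which escape X inactivation and were chosen after the Y-linked counts were seen, were 1.64-fold, 1.48-fold, 1.89-fold and 1.75-fold higher in the section labelled Ctrl than in Ctrl_HF. The male label and these counts differ for that section. Diet, L-NAME, sex and animal therefore cannot be separated in either comparison with Ctrl, whereas the comparison of TTg_HF with Ctrl_HF does not use that section.

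The transgene factors were compared first, since they check the genotype labels. All 4 were far higher in the TTg_HF section than in the other 2 sections. Tbx5 (ENSMUSG00000018263, chromosome 5, 119796514 to 119885220 in GRCm38) stood at 73.8 CPM in Ctrl, 48.2 CPM in Ctrl_HF and 717 CPM in TTg_HF, which was 14.9-fold above Ctrl_HF with a log2 ratio of 3.89 (3.8 to 3.99). Mef2c (ENSMUSG00000005583, chromosome 13, 83504017 to 83667079) stood at 79.7, 74.2 and 547 CPM, a log2 ratio of 2.88 (2.80 to 2.96). Gata4 (ENSMUSG00000021944, chromosome 14, 63198914 to 63271712) stood at 128 CPM in Ctrl, 148 CPM in Ctrl_HF and 749 CPM in TTg_HF, a log2 ratio of 2.34 (2.28 to 2.4). Hand2 (ENSMUSG00000038193, chromosome 8, 57320983 to 57324517) stood at 239, 215 and 998 CPM, a log2 ratio of 2.22 (2.17 to 2.27). For each of the 4 genes, every quadrant of the TTg_HF section lay above every quadrant of the other sections. UMIs of a transgene and of the animal's own gene are counted together under 1 symbol and cannot be told apart here. Between Ctrl_HF and Ctrl the list of the 4 factors had a median log2 ratio of −0.13 and did not stand apart from random lists (percentile 10.0).

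The factors were detected across the whole TTg_HF section. After every spot was thinned to 2500 UMIs, a UMI of Mef2c was present in 68.5% of 2127 spots, of Gata4 in 81.0%, of Tbx5 in 80.3% and of Hand2 in 87.9%. The same shares were 17.2%, 28.3%, 17.1% and 43.0% of 1931 spots in Ctrl and 16.8%, 31.7%, 12.1% and 41.4% of 2863 spots in Ctrl_HF. All 4 factors were found together in 43.4% of TTg_HF spots (41.3 to 45.5%, exact binomial interval), against 0.466% in Ctrl and 0.384% in Ctrl_HF. Chance alone would give 39.1% in TTg_HF if the 4 genes were found independently of each other. Without thinning, the shares of spots with all 4 factors were 15.3% in Ctrl and 7.68% in Ctrl_HF, and Tbx5 alone was found in 93.1% of TTg_HF spots. Thinning left out 30 spots of TTg_HF, 4 of Ctrl and 131 of Ctrl_HF.

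**Figure D1:**
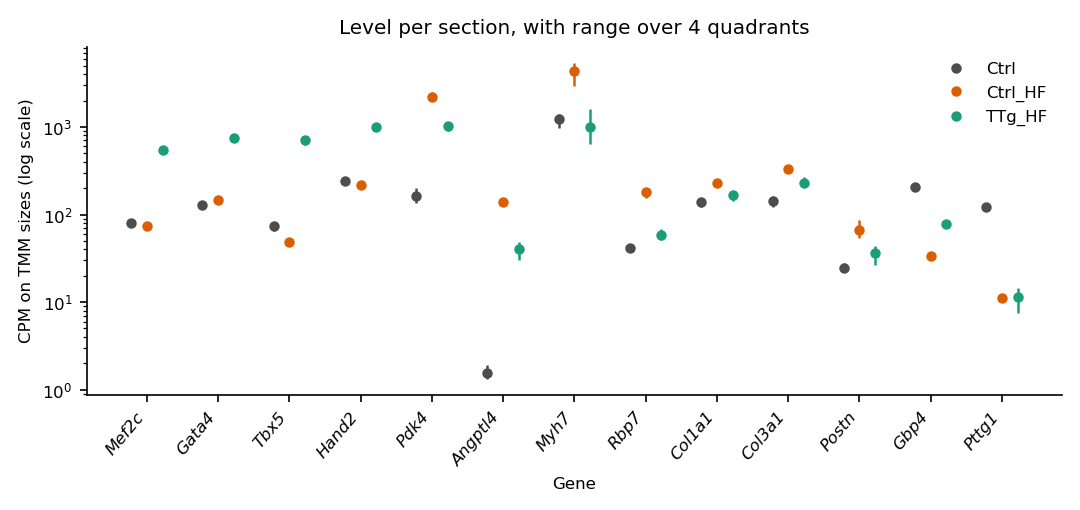
Level of 13 genes in each section, in CPM on a log axis; each dot is 1 section (Ctrl grey, Ctrl_HF orange, TTg_HF green) and each line spans the lowest to the highest of its 4 quadrants. The 4 factors are high in TTg_HF alone, Angptl4 runs from 1.57 CPM in Ctrl to 141 CPM in Ctrl_HF, and Myh7 from 4388 CPM in Ctrl_HF to 1005 CPM in TTg_HF.

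The first main comparison, Ctrl_HF against Ctrl, asks what the diet and L-NAME model does to the heart. Several genes of lipid use, Angptl4 and Pdk4 among them, were far higher in the Ctrl_HF section, the matrix and activated fibroblast lists were higher, and the beta myosin gene Myh7 was 3.58-fold higher. The lists of the interferon response and of MHC genes were lower. Of 10166 genes with at least 200 UMIs in both sections together, 530 were at least 1.5-fold higher and 342 at least 1.5-fold lower in Ctrl_HF. The quadrants of the sections were fully apart for 503 of the 530 and 326 of the 342. Quadrants were apart for 35.8% of all these genes, where random order would give 2.86%. Quadrants of a section share 1 animal and 1 library, so any difference between whole sections, technical ones included, sets them apart. The 2.86% is therefore no chance level for a difference between groups. Of 46 gene lists, 20 stood apart as higher and 12 as lower, where 2.3 would be outside the limits by chance if genes were independent. Real lists hold genes that vary together, so that a higher number arises without any effect.

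The list of PPAR-responsive lipid genes, which are switched on by fatty acids through PPAR receptors, had a median log2 ratio of 0.86, with 12 of 20 members at least 1.5-fold higher and 0 lower. Angptl4 (ENSMUSG00000002289, chromosome 17, 33774900 to 33781575), a secreted inhibitor of lipoprotein lipase, stood at 1.57 CPM (1.04 to 2.29) in Ctrl and 141 CPM (136 to 145) in Ctrl_HF, a log2 ratio of 6.48 (5.94 to 7.09). Pdk4 (ENSMUSG00000019577, chromosome 6, 5483351 to 5496278), which blocks the entry of pyruvate into the citric acid cycle, went from 164 CPM in Ctrl to 2179.5 CPM in Ctrl_HF, a log2 ratio of 3.73 (3.68 to 3.79). Acot1, an acyl-CoA thioesterase, was 7.54-fold higher and Ucp3, a mitochondrial uncoupling protein, 4.88-fold higher. The fatty acid oxidation list had a median of 0.41, with 5 of 20 members at least 1.5-fold higher. The adipocyte list was higher as well (0.52 over 6 members, of which 3 were at least 1.5-fold higher: Fabp4, Cidea and Lipe, with log2 ratios of 1.5, 1.03 and 0.87), but Fabp4 is also in the endothelial list, the median without that gene was 0.17, and the list did not stand apart with lower minimum counts (0.17). The largest ratios of the fatty acid oxidation list were those of Decr1 (1.24), the carnitine carrier Slc25a20 (0.91), Hadh (0.76) and Hadha (0.76).

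Genes of glucose use lay on the other side. The glucose uptake and glycolysis list had a median log2 ratio of −0.23, with 3 of 15 members at least 1.5-fold lower: the glucose transporters Slc2a1 (−1.07) and Slc2a4 (−0.77), and Eno3 (−0.77), the enolase of muscle. Hexokinase gene Hk2 stood at −0.51. That list no longer stood apart with lower minimum counts (median −0.21) or in the ventricular muscle region alone (−0.18). The oxidative phosphorylation list had a median of −0.26, and 0 of its 22 members passed 1.5-fold in either direction. Fbp2, the fructose bisphosphatase of muscle, was 5.69-fold higher in Ctrl_HF.

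The list of fibrillar collagens and matrix had a median log2 ratio of 0.59, with 11 of 24 members at least 1.5-fold higher and 0 lower. Col3a1 (ENSMUSG00000026043, chromosome 1, 45311538 to 45349706) stood at 141 CPM in Ctrl and 327 CPM in Ctrl_HF, a log2 ratio of 1.21 (1.14 to 1.28). Col1a1 (ENSMUSG00000001506, chromosome 11, 94936224 to 94953042) stood at 141 and 228 CPM, a log2 ratio of 0.70 (0.63 to 0.77). Col1a2 (0.93), Col5a1 (0.89) and Sparc (0.88), which encodes a collagen-binding protein, had the next largest ratios after Col3a1 among members with at least 200 UMIs. The activated fibroblast list had a median of 0.83, with 9 of 23 members at least 1.5-fold higher. Postn (ENSMUSG00000027750, chromosome 3, 54359267 to 54391041), a matrix protein of activated fibroblasts, stood at 24.8 CPM in Ctrl and 66.1 CPM in Ctrl_HF, a log2 ratio of 1.41 (1.26 to 1.57). Ccn5 stood at 2.08, Meox1, a transcription factor of activated fibroblasts, at 0.96, and Comp at 1.79, although the quadrants of the sections overlapped for Comp.

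Several other lists of non-muscle cells were higher too, and some were lower. The resident fibroblast identity list had a median log2 ratio of 0.38, with 5 of 20 members at least 1.5-fold higher (Dpep1, 1.02). The endothelial list had a median of 0.52 with 9 of 21 higher, among them the fatty acid binding protein gene Fabp4 (1.5), the tight junction gene Cldn5 (1.19) and the VEGF receptor gene Kdr (1.05). Its member Aqp1, a water channel gene, was lower (−1.28). The pericyte list had a median of 0.31 and the macrophage and monocyte list a median of 0.38, with 2 of 12 and 3 of 20 members at least 1.5-fold higher. The smooth muscle list (0.13) lay inside the random range, but stood apart in the ventricular muscle region alone (0.36) and with equal weights for spots (0.21). In the region led by Cilp, Cnn1, Tagln and Myh11 its median was −0.18, and in the region led by Irx2 and Cntn2 it was 0.37. The epicardial and mesothelial list had only 6 members with enough UMIs, a median of 1.30 and 3 members at least 1.5-fold higher, C3, Aldh1a2 and Wt1 with log2 ratios of 1.41, 1.56 and 1.2. With stricter minimum counts or in the ventricular muscle region alone, that list had a median of 1.41 or 1.71 and was not called, since under both settings it no longer met the rule. Besides the fibroblast, endothelial, pericyte, macrophage and smooth muscle lists, 9 lists of non-muscle cells had enough members, the epicardial list included; 5 of them stood apart as higher, 3 as lower, and 1 lay inside the random range. The lower ones were the lymphocyte list (−0.85 over 5 members), the lymphatic endothelial list (−0.40 over 6, with 2 at least 1.5-fold lower, Reln at −1.2 and Mmrn1 at −1.01) and the neuron and Schwann list (−0.40 over 7), and no member of the lymphocyte or the neuron and Schwann list passed the size rule. The lymphatic endothelial list did not stand apart with lower minimum counts (−0.39), nor the lymphocyte list under several settings, such as without section edges (−0.55), and the neuron and Schwann list lost its place under several settings and changed sign without section edges (0.16). The neutrophil list had a median of 2.06 over only 4 members, of which 1 passed the size rule, S100a9 (2.73), and was not called under several settings.

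Heart muscle genes differed in both directions. The list of cardiomyocyte stress and fetal genes had a median log2 ratio of 0.29, with 6 of 16 members at least 1.5-fold higher. Myh7 (ENSMUSG00000053093, chromosome 14, 54970684 to 54994626), the beta myosin heavy chain of the fetal mouse ventricle, stood at 1226 CPM in Ctrl and 4388 CPM in Ctrl_HF, a log2 ratio of 1.84 (1.82 to 1.86). The secreted stress factor Gdf15 stood at 1.36, the skeletal actin gene Acta1 at 0.93 and Ankrd1 at 0.91. The sarcomere list had a median of −0.24 with 1 of 19 members at least 1.5-fold lower, the alpha myosin gene Myh6 (−0.66), and it lost its place outside the random range in the ventricular muscle region alone (−0.22). The ventricular cardiomyocyte list had a median of −0.30. The list of calcium handling and electrical coupling had a median of −0.25, with 3 of 20 members at least 1.5-fold lower: the potassium channel genes Kcnip2 (−1.17) and Kcnd2 (−1.02), and Ryr2 (−0.60), the calcium release channel.

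The interferon response list had a median log2 ratio of −0.55, with 9 of 22 members at least 1.5-fold lower and 0 higher. Its members Iigp1 (−1.92), Igtp (−1.80) and Gbp3 (−1.48) encode interferon-induced GTPases. Others outside the list, Gbp4 (−2.61), Irgm2 (−1.90) and Gbp6 (−1.76), were lower too. Gbp4 stood at 208 CPM in Ctrl and 34.0 CPM in Ctrl_HF. The list of MHC class I and II had a median of −0.52 with 6 of 14 lower, and Tap1, which carries peptides to class I molecules, had the lowest ratio (−1.42). The list of inflammatory cytokines and chemokines had a median of 0.42 with 3 of 9 members higher, among them the chemokine genes Ccl8 (2.21) and Ccl11 (1.58), while Il33 was lower (−0.81). That list did not stand apart in the ventricular muscle region alone (0.28).

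The circadian clock list had a median log2 ratio of −0.22, with 3 of 17 members at least 1.5-fold lower, which were Hlf (−1.0), Nr1d2 (−0.66) and Dbp (−0.64), and it did not stand apart with section edges left out (−0.14). The glucocorticoid and fasting response list stood at −0.44, with 4 of 17 members lower, such as Klf15 (−0.89), and 2 higher, which were Sgk1 (1.06) and Cdkn1a (1.03). The nitric oxide and cGMP signalling list stood at 0.34 with 2 of 14 members higher, the natriuretic peptide receptor gene Npr3 (0.99), whose quadrants overlapped, and the caveolin gene Cav1 (0.76). The unfolded protein response list stood at 0.20, with 1 of 22 members higher and 1 lower. Among single genes outside these lists, Ogdhl was 13.7-fold and Haus3 5.30-fold higher. The securin gene Pttg1 (−3.47) stood at 123 CPM in Ctrl and 11.1 CPM in Ctrl_HF. Cyp26b1 (−2.58), Tmem144 (−2.31), Cyfip2 (−2.28), Hddc3 (−2.19) and Cbr2 (−1.86) were also among the genes with the lowest ratios. The Y-linked genes Eif2s3y, Ddx3y, Uty and Kdm5d were at least 507-fold, 419-fold, 164-fold and 147-fold higher in Ctrl_HF, computed against a floor of 3 counts in the Ctrl section.

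**Figure D2:**
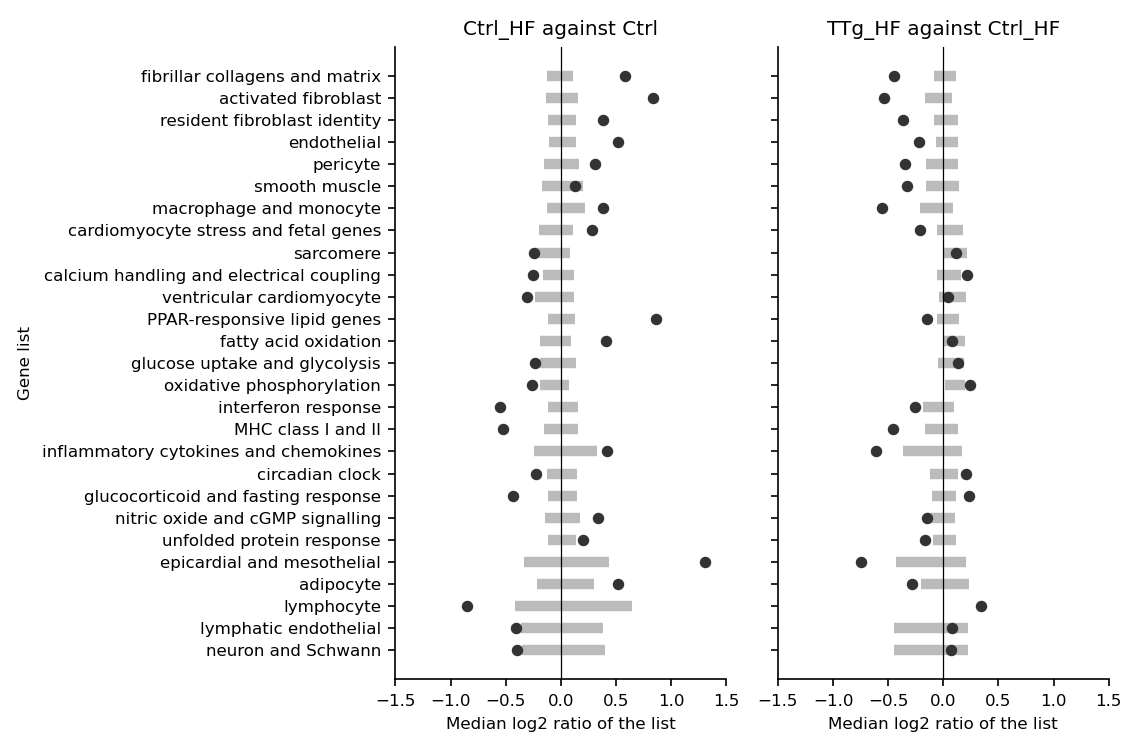
Median log2 ratio of 27 gene lists in the model comparison (left) and the transgene comparison (right); each dot is the median of 1 list (the neutrophil list, at 2.06 and −3.8, is outside the axis and not drawn), the grey bar is the central 95% of 10000 random lists matched on size and mean expression (none on the right for the lymphocyte list, with only 3 members), and the vertical line marks no difference. The matrix list lies at 0.59 on the left and −0.45 on the right, and the interferon response list lies at −0.55 and −0.26.

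The second main comparison, TTg_HF against Ctrl_HF, asks what the transgene adds under the same diet and L-NAME. Besides the 4 factors, the TTg_HF section had a lower level of Myh7 and lower medians of the matrix, activated fibroblast and macrophage lists. Myh7 stood at 1005 CPM in TTg_HF against 4388 CPM in Ctrl_HF, a log2 ratio of −2.13 (−2.16 to −2.10), which was close to the 1226 CPM of Ctrl. Of 9883 genes with at least 200 UMIs in both sections together, 136 were at least 1.5-fold higher and 329 at least 1.5-fold lower in TTg_HF. Quadrants were fully apart for 124 and 278 of them, and for 26.1% of all genes. Of 45 lists, 6 stood apart as higher and 21 as lower, where 2.25 would by chance.

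The list of fibrillar collagens and matrix had a median log2 ratio of −0.45, with 5 of 24 members at least 1.5-fold lower and 0 higher. Mfap4 (−1.41), which binds elastic fibres, and Fbln1 (−0.88), Fbn1 (−0.65) and Col14a1 (−0.64) had the lowest ratios. Col1a1 stood at 168 CPM in TTg_HF against 228 CPM in Ctrl_HF (−0.44, −0.52 to −0.36), and Col3a1 at 231 against 327 CPM (−0.50, −0.57 to −0.44). The activated fibroblast list had a median of −0.54 with 9 of 23 members at least 1.5-fold lower. Cilp (−1.35), a matrix protein of cartilage and activated fibroblasts, Ccn5 (−0.97) and Comp (−0.90) were among them, and Postn stood at 35.9 against 66.1 CPM (−0.88, −1.04 to −0.72) and Meox1 at −0.75. Quadrants overlapped for Comp, and within the ventricular muscle region alone its ratio was 0.23.

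Several other lists of non-muscle cells were lower too. The macrophage and monocyte list had a median log2 ratio of −0.56, with 5 of 19 members at least 1.5-fold lower, such as F13a1 (−0.89) and the complement genes C1qa (−0.77) and C1qb (−0.77). The resident fibroblast identity list stood at −0.37 with 3 of 20 lower, such as Pi16 (−0.88) and Serping1 (−0.73). The endothelial list stood at −0.22 with 2 of 21 lower, such as Fabp4 (−0.80), while Aqp1 had the highest ratio (0.50), which is under 1.5-fold. The pericyte list stood at −0.35 with 2 of 12 lower and the smooth muscle list at −0.33 with 1 of 12 lower; the latter did not stand apart once the smooth muscle and blood clusters were left out (−0.11), a setting chosen after seeing the data. The epicardial and mesothelial list stood at −0.74 with 2 of 6 lower, C3 (−1.28) and Aldh1a2 (−0.62, with overlapping quadrants), and was not called with stricter minimum counts (−0.62) or in the ventricular muscle region alone (−0.54). Of 8 such further lists of non-muscle cells, the epicardial list included, 4 stood apart as lower, 0 as higher and 4 lay inside the random range, among them the lymphatic endothelial list (0.08) and the neuron and Schwann list (0.07). Both medians depended on the setting: the lymphatic endothelial list stood apart as higher without the smooth muscle and blood clusters (0.26) but lay at −0.20 with stricter minimum counts and at −0.25 without section edges, and the neuron and Schwann list lay at −0.05 after thinning to the shallowest section and at −0.13 without those clusters. The lymphocyte list had only 3 members with enough UMIs (median 0.34), and the neutrophil list had a median of −3.8 over 4 members, with S100a9 at 1 UMI in TTg_HF against 283 in Ctrl_HF (−7.10, −12.4 to −4.61), and was not called with stricter minimum counts, after thinning to the shallowest section (−5.47) or without the smooth muscle and blood clusters (−4.58).

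Heart muscle lists lay on both sides of 0 or inside the random range. The sarcomere list (0.12) and the ventricular cardiomyocyte list (0.04) lay inside the random range, the latter with a sign that turned under scaling by total UMIs (−0.01), with equal weights for spots (−0.01) and in the ventricular muscle region (−0.05). For the sarcomere list the random range was 0.004 to 0.217, wholly above 0. Lying inside it therefore does not mean no difference. The list of calcium handling and electrical coupling had a median log2 ratio of 0.21, with 2 of 20 members at least 1.5-fold higher, among them Kcnd2 (0.83), whose quadrants overlapped. The gap junction gene Gja1 stood at 0.48. The list of cardiomyocyte stress and fetal genes stood at −0.21 with 2 of 16 members lower, Myh7 and Gdf15 (−1.66). The oxidative phosphorylation list stood at 0.24 with 0 of 22 members past 1.5-fold, and it did not stand apart in the ventricular muscle region alone (0.15).

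The PPAR-responsive and fatty acid oxidation lists were higher in TTg_HF than in Ctrl, while against Ctrl_HF only the PPAR-responsive list stood apart, as lower (percentile 0.04). The PPAR-responsive list had a median log2 ratio of −0.15 against Ctrl_HF with 3 of 20 members at least 1.5-fold lower, Angptl4 (−1.80), Pdk4 (−1.08) and Acot1 (−0.65), and a median of 0.59 against Ctrl, with 10 of 20 members at least 1.5-fold higher. The adipocyte list stood at −0.29 against Ctrl_HF with 1 of 5 members lower, Fabp4. Pdk4 stood at 1031 CPM and Angptl4 at 40.3 CPM in TTg_HF. The fatty acid oxidation list (0.08, with 0 of 20 members counted in either direction) and the glucose uptake and glycolysis list (0.13) lay inside the random range against Ctrl_HF. For fatty acid oxidation that range, 0.007 to 0.199, was wholly above 0. The MHC class I and II list was lower again, with a median of −0.45 and 5 of 14 members at least 1.5-fold lower, such as the class II invariant chain gene Cd74 (−0.81). The interferon response list stood at −0.26 with 2 of 22 lower, but at −0.08 in the ventricular muscle region alone, where it did not stand apart. Gbp4 was higher in TTg_HF than in Ctrl_HF (1.21). The list of inflammatory cytokines and chemokines stood at −0.61 with 3 of 10 lower, such as Ccl8 (−1.64).

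The circadian clock list had a median log2 ratio of 0.21, with 3 of 17 members at least 1.5-fold higher, Dbp (0.73), Hlf (0.68) and Nr1d1 (0.63), and 1 lower, Arntl (−0.91). The glucocorticoid and fasting response list stood at 0.23 with 1 of 17 members lower, Cdkn1a (−0.85). The unfolded protein response list stood at −0.16 with 0 of 22 members counted in either direction, and the nitric oxide and cGMP signalling list (−0.15) lay inside the random range unless the sections were thinned to about the same total of UMIs (−0.19). After the factors, the highest single ratios among genes with at least 20 CPM in the higher section were those of Fbxo44 (1.97), Pla2g5 (1.92), Slc25a29 (1.70), Cenpf (1.58), Pigv (1.5), Scn4a (1.48), C1qtnf6 (1.47) and Isoc2a (1.39). The lowest included Ogdhl (−3.26), Haus3 (−2.31), B3galt2 (−1.65), the retinol binding protein gene Rbp7 (−1.62), the endothelin gene Edn3 (−1.61), Ephb1 (−1.44) and Nedd1 (−1.35).

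Against Ctrl, the TTg_HF section had 195 genes at least 1.5-fold higher and 258 at least 1.5-fold lower of 9523. The matrix list stood at 0.09 and inside the random range (percentile 93.6), though not under every setting, with 3 of 23 members higher and 4 lower, while the activated fibroblast list stood at 0.27 and apart. The resident fibroblast identity list (−0.04) lay inside the random range. The fatty acid oxidation list stood at 0.52 with 8 of 20 members at least 1.5-fold higher. The interferon response list stood at −0.69 and the MHC class I and II list at −1.03, with 12 of 14 members at least 1.5-fold lower.

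Matrix transcripts took a larger share of a spot's UMIs in the Ctrl_HF section. At 2500 UMIs per spot, the matrix list took a median of 0.24% of a spot's UMIs in Ctrl, 0.36% in Ctrl_HF and 0.28% in TTg_HF. The interquartile ranges were 0.16 to 0.36%, 0.28 to 0.48% and 0.2 to 0.4%. A general rise in level can therefore put more spots above a fixed threshold, and how evenly the transcripts lay over a section was not measured. Spots above 0.6%, the 95th percentile of Ctrl, made up 3.78% of spots in Ctrl (2.97 to 4.73%, exact binomial interval), 10.3% in Ctrl_HF (9.18 to 11.4%) and 4.28% in TTg_HF (3.46 to 5.23%). In the ventricular muscle region alone, where the 95th percentile of Ctrl was 0.4%, the shares were 4.18% in Ctrl (2.70 to 6.16%), 17.5% in Ctrl_HF (14.9 to 20.3%) and 9.33% in TTg_HF (7.00 to 12.1%), so that TTg_HF lay above Ctrl there. The Ctrl value is under 5% because many spots tie at the threshold. All these intervals treat spots as independent draws, which spots of 1 section are not, and they cover no spread between animals. Summed over a section, the matrix list took 0.287%, 0.402% and 0.308% of UMIs, and the sarcomere list took 11.6%, 8.80% and 10.2%. Clustering gave 3 regions, 1 led by Cilp, Cnn1, Tagln and Myh11, 1 by Irx2, Cntn2 and hemoglobin genes, and 1 by Mstn, Slc9a2 and Kcnd2. The last, the smallest in spots, had no leading gene from any cell type list and is called the ventricular muscle region here. The plan was to use the largest region led by ventricular muscle genes. The sarcomere list took 11.2%, 11.7% and 12.1% of UMIs in the 3 regions of Ctrl, so the name does not set the last apart from other muscle. Thinning kept 574 of its 577 spots in Ctrl, 773 of 890 in Ctrl_HF and 536 of 542 in TTg_HF. The matrix list was higher in Ctrl_HF than in Ctrl in each of the 3 regions, with medians of 0.41, 0.62 and 0.53, and lower in TTg_HF than in Ctrl_HF, with medians of −0.37, −0.39 and −0.37.

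**Figure D3:**
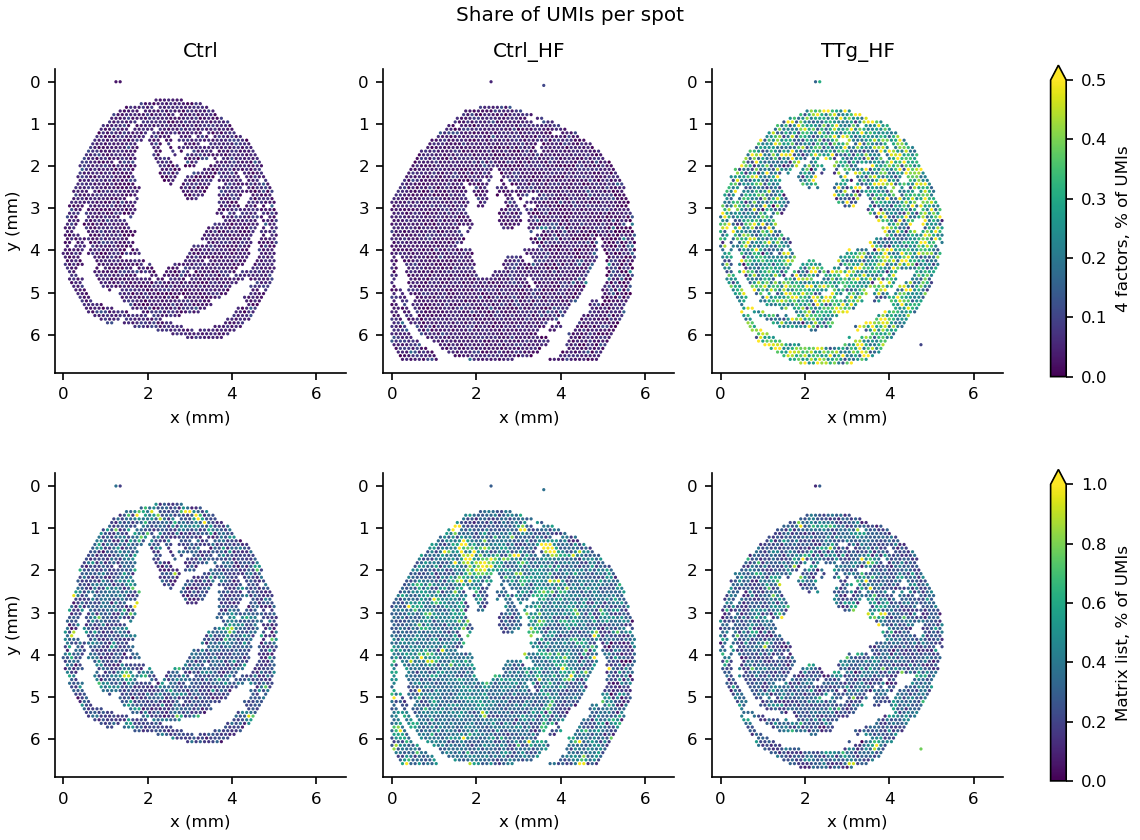
Share of UMIs per spot, without thinning, on the 4 factors (top) and on the matrix list (bottom) in the Ctrl, Ctrl_HF and TTg_HF sections; axes are positions on the slide in mm, each dot is 1 spot, and colours are capped at 0.5% and at 1%. The factors fill the whole TTg_HF section, and spots rich in matrix transcripts are most frequent in Ctrl_HF, where 10.3% of thinned spots lie above the threshold.

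The ratios of the model and transgene comparisons were negatively correlated across genes. Across 9869 genes, which are not independent replicates, r was −0.57 (Spearman's rho −0.57). Both comparisons use the Ctrl_HF section with opposite signs. In simulations, 3 sections that varied independently with the same spread gave −0.49, and counting noise alone gave −0.39. With 3 sections, r is fixed by the variances of the 3 ratios. These were 0.143 for Ctrl_HF against Ctrl, 0.0943 for TTg_HF against Ctrl_HF and 0.105 for TTg_HF against Ctrl. Independent sections with unequal spread can give the observed r, so neither r nor the covariance shows a reversal. The covariance was −0.066, against −0.0041 from counting noise alone, and differences between animals that come with no treatment also enter it. Of 519 genes at least 1.5-fold higher in Ctrl_HF than in Ctrl, 180 were at least 1.5-fold lower in TTg_HF than in Ctrl_HF, which is 34.7% against 26.7% in the simulation, and unrelated lists would share 17.2 genes. Of 286 genes that were lower in Ctrl_HF, 66 were higher in TTg_HF, which is 23.1% against 27.0% in the simulation, and unrelated lists would share 3.88. The first share lay above the simulated one and the second below it. In the simulation, which holds no effect, sharing the Ctrl_HF section gave most of the first excess over unrelated lists and all of the second. These overlaps therefore do not show a reversal. The Ctrl_HF section cannot be split into separate libraries. The simulation shares that section too, and it assumes the same spread in all 3 sections.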

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

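The alternatives without smooth muscle and blood clusters and without genes of chromosomes X and Y were chosen after seeing the data. No paired analysis was possible because each group has 1 section and no test was made. Of the list medians under alternatives, 795 kept their direction and side, 31 were no longer called as standing apart and 14 were newly called. A further 18 moved and 1 reversed, that of the neuron and Schwann list in Ctrl_HF against Ctrl (0.16 with section edges left out). A list with too few members has no random range, so some calls were lost or gained through the number of members alone. In Ctrl_HF against Ctrl, the epicardial list lost its call in the ventricular muscle region at 1.71, with 3 members. In TTg_HF against Ctrl_HF, the lymphocyte list had 3 members in the main setting and was called only with lower minimum counts (0.34). Of the named gene ratios, 3241 stayed within their interval, 357 moved and 1 reversed, that of Comp in TTg_HF against Ctrl_HF (0.23 in the ventricular muscle region alone). The cause was not tested for any result below, except that stricter or looser limits count fewer or more genes by construction.

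With a minimum of 50 UMIs, 566 genes were at least 1.5-fold lower in Ctrl_HF than in Ctrl, 258 higher and 586 lower in TTg_HF than in Ctrl_HF, and 339 higher and 485 lower in TTg_HF than in Ctrl. With 1000 UMIs the counts were 236 and 165, 57 and 89, and 90 and 79. With a size of 2-fold they were 165 and 87, 36 and 72, and 46 and 74. In the ventricular muscle region alone, 299 genes were higher and 224 lower in Ctrl_HF than in Ctrl, and 134 were lower in TTg_HF than in Ctrl_HF.

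The matrix list in TTg_HF against Ctrl (0.09) stood apart as higher with a minimum of 10 UMIs for list members in place of 50 (0.12), with equal weights for spots (0.15) and without smooth muscle and blood clusters (0.15). Spots above the matrix threshold made up 9.53% of Ctrl, 23.7% of Ctrl_HF and 11.4% of TTg_HF at the 90th percentile of Ctrl, 5.01%, 14.2% and 6.26% without thinning, 5.02%, 14.2% and 5.77% without section edges, 4.18%, 17.5% and 9.33% in the ventricular muscle region, and 4.33%, 14.3% and 5.23% without smooth muscle and blood clusters. A resolution of 1.0 gave 9 clusters in place of 3.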

Other observations

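All tests of explanations in this part were chosen only after the result was seen.

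Within the TTg_HF section, the 4 factors varied together from spot to spot, with Spearman's rho between pairs of factors of 0.174 to 0.193, against −0.051 to 0.026 in Ctrl and −0.014 to 0.038 in Ctrl_HF. Spots are not independent replicates. The sum of the 4 factors had a rho of −0.107 with the matrix list, −0.098 with the endothelial list, −0.073 with the smooth muscle list, −0.068 with the resident fibroblast identity list, 0.050 with the sarcomere list, −0.034 with the activated fibroblast list, −0.021 with the ventricular cardiomyocyte list and 0.0067 with the macrophage and monocyte list. When these spots were ordered by factor UMIs and split into 4 equal sets, the matrix list took 0.325% of UMIs in the lowest set (mean 3.04 factor UMIs after thinning) and 0.281% in the highest (12.7), and the resident fibroblast identity list took 0.238% and 0.212%. The ventricular muscle region held a mean of 8.53 factor UMIs per thinned spot, against 6.84 in the region led by Cilp, Cnn1 and Tagln and 7.06 in the region led by Irx2 and Cntn2. In Ctrl the means had the same order, from 1.42 in the ventricular muscle region to 1.2 in the region led by Cilp, Cnn1 and Tagln, and in Ctrl_HF they lay between 1.21 and 1.27.

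Several genes stood out in a single section and in all 4 of its quadrants. Ogdhl ranged from 35.4 to 49.0 CPM over the quadrants of Ctrl_HF, against 1.99 to 4.03 in Ctrl and at most 5.84 in TTg_HF. Haus3 ranged from 48.5 to 56.6 CPM in Ctrl_HF, against at most 12.1 CPM in any quadrant of the other sections. B3galt2 ranged from 5.82 to 10.7 CPM in TTg_HF, against 26.2 to 28.9 in Ctrl and 26.4 CPM over the whole of Ctrl_HF, whose quadrants also lay apart from those of TTg_HF.

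The section labelled Ctrl, given as male, held 0 UMIs of 11 Y-linked genes. Too little depth is argued against, since 3709.7 UMIs would stand there at the lower of the levels in the other sections. A female animal behind that section is a candidate explanation: all 4 X-linked genes that escape inactivation (Ddx3x, Eif2s3x, Kdm6a and Kdm5c) were over 1.2-fold higher in it than in both other sections, while 280 X-linked genes had a median log2 ratio of only 0.04 against Ctrl_HF. The tables do not show whether the label of sex or the section is out of place.

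The medians of the resident fibroblast, endothelial, pericyte, smooth muscle and macrophage lists were above 0 in Ctrl_HF against Ctrl and below 0 in TTg_HF against Ctrl_HF, as that of the matrix list was, whereas 3 of 9 other non-muscle cell type lists stood apart as lower in the first comparison and 4 of 8 lay inside the random range in the second. A share of heart muscle RNA stays open for the activated fibroblast list: it lay 0.45 above the resident fibroblast list (0.02 to 0.76) in the first comparison and −0.32 from the endothelial list (−0.60 to −0.03) in the second, but its other gaps to these lists (0.31 and −0.17) had intervals that held 0, as did all such gaps inside each of the 3 regions (0.17 to 0.32 in the first comparison and −0.32 to 0.11 in the second). For the 5 lists it stays open too: the largest gap between them was 0.39 in the first (endothelial against smooth muscle, 0.01 to 0.76), but 0.43 with an interval of −0.08 to 0.82 without Des, which heart muscle also expresses, and 0.34 in the second (macrophage against endothelial), where 0 of 10 pairs were apart. Against these 5 lists pooled, the lymphocyte (−1.22, −2.21 to −0.64), neutrophil (1.69, 0.34 to 2.43) and epicardial (0.94, 0.10 to 2.88) lists lay apart in the first comparison. In the second, the lymphatic endothelial (0.71, 0.05 to 1.2) and neuron and Schwann (0.36, 0.06 to 1.14) lists did. Each of these gaps rests on only 4 to 6 genes. The median level of those genes in the higher section was 4.08 to 7.70 CPM. That is above the 99th percentile of odorant and vomeronasal receptor genes, which was 0.421 CPM in Ctrl, 0.283 in Ctrl_HF and 0.202 in TTg_HF. The medians of the last pair of lists changed sign under other settings. With so few genes, these gaps do not decide on the share of heart muscle RNA. Diet with L-NAME, the factors and differences between single animals also stay open, as untested.

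A total of 277 autosomal genes set the section labelled Ctrl apart from both others by 1.5-fold. Unequal background of the probes stays open. The median level of the 277 genes in the higher section was 38.3 CPM. The bound was 4.21 CPM, 10 times the 99th percentile of odorant and vomeronasal receptor genes in Ctrl. That bound cannot decide it, since the minimum count for these genes put 100% of them above it. Of 1178 receptor genes, 712 had a UMI in Ctrl, 167 in Ctrl_HF and 226 in TTg_HF. Summed, they stood at 97.0, 60.2 and 47.8 CPM. The 277 genes formed 15 pairs of neighbours on a chromosome, such as Resf1 with Bicd1 and Hddc3 with Man2a2. At most 12 pairs arose in 10000 random sets (median 4). A genetic difference between animals of the hybrid strain could give such pairs. However, the genes that set Ctrl_HF apart, 166 higher and 74 lower, formed 7 pairs (random median 3), which 489 of 10000 random sets reached. Those of TTg_HF, only 31 higher and 60 lower, formed 0. The random median was 0 there as well, so that count cannot speak for or against a genetic difference. Igtp with Irgm2, Psmb9 with Tap1 and Tap1 with Psmb8 are pairs of interferon or antigen presentation genes, so neighbours regulated together stay open. Igtp and Irgm2 both encode interferon-induced GTPases, so pairs of related genes with unlike symbols remained in the count. The number of pairs without related or jointly regulated genes was not computed. The excess over the random sets therefore cannot decide on a genetic difference. Diet, L-NAME and sex stay open too, as untested, because each differs along with this section.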
